A study of Homo sapiens with 24 samples.

How the data were processed

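The series holds 24 RNA sequencing libraries of MCF-7 cells, an estrogen receptor positive breast cancer line that expressed a GFP-tagged ribosomal protein (GFP-RPL10a). Ribosome-bound RNA was taken from these cells by translating ribosome affinity purification (TRAP). Per the labels' protocols, cells spent 48 h in hormone-depleted medium with 2% charcoal-stripped serum, were plated on low attachment dishes, formed spheres for 24 h and were then treated. The labels give 8 groups of 3 libraries: monoculture or coculture, each with vehicle (UT), 10 nM estradiol (E2), fulvestrant (ICI) or 100 nM tamoxifen, which other labels name 4OHT. The dose of fulvestrant and the duration of treatment cannot be read from the labels with certainty. The coculture partner is given as human mesenchymal stem cells in the growth protocol and as an osteoblast line in the series design text, and is called the stromal partner here. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between libraries.

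Per the submitters' processing notes, reads were handled with bcl2fastq 2.17, STAR, RSEM 1.2.28 and DESeq2 on the GRCh38 build, with paired-end reads from a NextSeq 550 after Nextera XT library preparation. The file of the authors holds log2 values per gene, normalized across all 24 libraries in 1 step, from -2.74 to 16.2. The deposited log2 values look like regularised log values, but the transform, the annotation and any filter are not stated. Of 36959 genes listed, 16998 were at 0 in all libraries and 0 genes were at 0 in only some. The file keeps no read counts, so the sequencing depth per library is unknown and tests on counts could not be run. Sums of the values taken back from the log scale ran from 257590 to 471391 per library and are not a depth. 27 gene names had been turned into dates and 2 names occurred more than once, and these were kept as separate entries. 16 genes of X inactivation or the Y chromosome were left out.

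Values were used on the deposited log2 scale with no pseudocount. A plan written for linear values asked for a mean of at least 20, which was applied to the values taken back from the log scale (mean over all libraries), leaving 3214 of 19945 genes. Group means of the 8 groups were fitted in 1 model with limma 3.58.1 (trend, moderated, two-sided) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Comparisons were each treatment against vehicle within a culture, the difference of these effects between cultures (interaction), coculture against monoculture within each treatment and as the mean of the 4 treatments, and 4OHT against fulvestrant and fulvestrant against E2 within each culture. Errors are standard errors (SE) of the fit unless named as SD, and intervals are at 95%. The median log2 change of all tested genes was off 0 by more than 0.1 in several comparisons, and changes are given there relative to that median, while the tests are of the unshifted change. Where counts or members of lists are given at a lower filter, the mean value was at least 4 (8843 genes).

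20 gene lists were fixed: estrogen-induced, estrogen-repressed, luminal epithelial, basal and stem, epithelial-mesenchymal transition, stromal and mesenchymal stem cell, osteoblast, adipocyte, blood and endothelial, FGF and PDGF signalling, Polycomb repressive complex (PRC2), cell cycle, interferon, NF-kB and inflammation, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and amino acid stress, TGF-beta and YAP responsive, handling stress, and mitochondrially encoded genes. Lists with at least 3 tested members were tested with camera in limma (preset correlation 0.01, and an estimated correlation as the alternative), with Benjamini-Hochberg over the lists of a comparison. List medians are relative to the median of all genes. Genes to be named were set by rule: ESR1, GREB1, TFF1, PGR, RPL10A and EZH2 always, then up to 8 rising and 8 falling genes with the largest log2 change among those past the threshold, with a mean value of at least 100 in the higher group and no overlap of the compared groups in any library (for the mean over treatments, the same direction in all 4). For secondary comparisons the first of these could be named alone. Up to 4 members with the smallest adjusted p were added for each list described. Pseudogenes, antisense, small RNA and histone symbols were left out of the rule. The comparisons, tests, lists, rule and most alternatives were set before the data were examined.

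Alternatives were no filter, filters of 4 and 100, TMM scaling, quantile normalization, array weights, a replicate block, a fit of only the compared groups, leaving out each library, and a correction for GC content and transcript length by lowess (span 0.3) with GENCODE 29 annotation, available for 3178 genes (98.88% of those tested). The filter of 4 and the GC and length correction were chosen after seeing the data. Where a library was left out of a group, the remaining libraries were assumed to vary like the other groups. Replicate numbers were checked for pairing: over 84 pairs of libraries with the same number and of different groups, correlations of deviations from the group mean had a median of -0.00259 (from -0.541 to 0.406), so the numbers were not used as pairs. The fit was tested on simulated data: at 3 libraries per group, log2 changes of 0.5, 1, 2 and 3 put into the monoculture fulvestrant comparison were called in 0%, 40%, 90% and 100% of genes, and in 4%, 12%, 80% and 88% for the interaction. Simulated noise was independent between genes, with the same spread in all libraries. Real deviations had SDs of 0.18, 0.532 and 0.523 in the monoculture fulvestrant libraries and 0.132 to 0.206 in those of 4OHT, so these rates are a rough guide. Figures and annotation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.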

Results

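Ribosome-bound RNA of MCF-7 spheres was compared between treatments that act on the estrogen receptor, and between spheres grown alone and with a stromal partner. The series title puts the question as how a bone environment affects the plasticity of these cells. Culture was the main difference between libraries: the first principal component held 71.03% of the variance and placed 24 of 24 libraries on the side of their own culture. Spearman correlations between libraries over the tested genes were 0.787 to 0.970 between replicates in monoculture, 0.729 to 0.925 in coculture and 0.071 to 0.447 between cultures.

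Fulvestrant, an antagonist that leads to degradation of the receptor, lowered estrogen target genes in monoculture. GREB1, an estrogen-induced cofactor of the receptor, fell from a mean log2 value of 7.11 ± 0.18 (SD) to 3.48 ± 0.69, a 12.4-fold change (n = 3 libraries per group). The median gene moved by 0.22. Relative to it GREB1 changed by -3.85 ± 0.32 (SE, adjusted p = 1.34e-08, limma with Benjamini-Hochberg) and PGR, the progesterone receptor gene, by -2.75 ± 0.28 (adjusted p = 1.09e-06). IGFBP4, a binding protein of insulin-like growth factors (-3.04 ± 0.34), the cadherin CELSR2 (-2.87 ± 0.37), and the GTPase RAB31 (-2.66 ± 0.36) also fell. So did the keratin KRT8 (-2.65 ± 0.36), the protease PRSS23 (-2.14 ± 0.31), TPD52L1 (-2.03 ± 0.31), the glycolytic enzyme PKM (-1.86 ± 0.33) and the fatty acid elongase ELOVL2 (-1.83 ± 0.39), with adjusted p from 6.02e-06 to 0.017. Rising genes changed less: ID1, an inhibitor of DNA binding induced by BMP signals (1.51 ± 0.37), GPATCH2 (1.27 ± 0.35), and the receptor S1PR3 (1.22 ± 0.36). Also higher were the Golgi and centrosome proteins AKAP9 (1.01 ± 0.33), GCC2 (0.97 ± 0.32) and GOLGA4 (0.81 ± 0.26), the gluconeogenic enzyme FBP1 (0.94 ± 0.25) and NQO1 (0.89 ± 0.31), with adjusted p from 0.00812 to 0.0383. ESR1, the receptor gene itself (0.62 ± 0.29, adjusted p = 0.0921), TFF1 (-0.86 ± 0.34, adjusted p = 0.289) and RPL10A (0.07 ± 0.31, adjusted p = 0.598) did not pass.

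Of 22 tested estrogen-induced genes, 14 fell with fulvestrant in monoculture (16 adjusted over the list alone). The list median was -1.52 (camera adjusted p = 2.38e-25, and 3.6e-08 with an estimated correlation). Among 6 estrogen-repressed genes, the coactivator NCOA3 (0.66 ± 0.19) and the Notch target HES1 (1.22 ± 0.32) rose, 3 adjusted over the list alone. That list had a median of 0.53 (camera adjusted p = 0.00356, but adjusted p = 0.0572 with an estimated correlation). 0 of 11 cell cycle genes passed (2 lower adjusted over the list alone), with RRM2 at -1.61 ± 0.45 and MCM7 at -1.18 ± 0.32 as the nearest. The list median was -0.58 (camera adjusted p = 0.00839, adjusted p = 0.0572 with an estimated correlation). Of 20 luminal genes, the keratins KRT8 and KRT18 (-1.15 ± 0.22) fell, with 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.197). The immediate early gene EGR1 (1.09 ± 0.31) and the matrix gene FN1 (-1.61 ± 0.34) passed within lists not called at the filter of 20. By camera the stromal list, which holds FN1, was called at the filter of 4 (adjusted p = 2.31e-05) and with no filter (0.0052). It was also called with the GC and length correction (0.0353) and without vehicle replicate 2 (0.0287) or fulvestrant replicate 2 (0.0171). 0 of 12 hypoxia and glycolysis genes passed, alone or over all genes (list median -0.58, camera adjusted p = 0.0447, adjusted p = 0.575 with an estimated correlation).

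In all, 38 genes were higher and 97 lower in this comparison by limma. The lower share was 71.9%, against 89.6% with TMM scaling, 83.6% with quantile normalization and 85.3% with the GC and length correction. It was 54.5% at the filter of 100, 50.3% with array weights (250 higher, 253 lower) and 49.9% without fulvestrant replicate 3 (280 and 279). Changes followed GC content across genes (Spearman -0.535, and -0.0169 after the correction), from a median of 0.437 in the decile of lowest GC to -0.595 in the highest, and the correction kept 54.1% of the calls. Fulvestrant replicates 2 and 3 stood apart: their correlation with each other was 0.787, the first component put them at -70.4 and -31.4, and their deviations from the group mean followed GC with -0.475 and 0.48. The count was 77, 37 and 42 without vehicle replicate 1, 2 and 3, and 40, 44 and 559 without fulvestrant replicate 1, 2 and 3. Calls of GREB1, PGR, IGFBP4, CELSR2, RAB31, KRT8, PRSS23, TPD52L1, PKM and FBP1 held without any 1 of these 6 libraries. Others were lost: without vehicle replicate 1 S1PR3, GCC2 and ELOVL2 (adjusted p 0.06 to 0.0623). Without vehicle replicate 2 the lost genes were FN1, ID1, KRT18, GPATCH2, HES1, EGR1, S1PR3, ELOVL2, GOLGA4, GCC2, NQO1 and AKAP9 (0.0551 to 0.125). Without vehicle replicate 3 the calls of EGR1, NCOA3, GPATCH2, S1PR3, GOLGA4, GCC2, KRT18, AKAP9, FN1 and NQO1 were lost (adjusted p 0.0517 to 0.188). The same held without fulvestrant replicate 1 for EGR1, ID1, GOLGA4, ELOVL2, GCC2, AKAP9, S1PR3 and NQO1 (0.0509 to 0.131). It also held without fulvestrant replicate 2 for HES1, EGR1, GPATCH2, S1PR3, GOLGA4, NQO1, AKAP9 and GCC2 (0.0974 to 0.299). Without fulvestrant replicate 3 the calls of MCM7 (adjusted p = 0.0171) and ESR1 (adjusted p = 0.0321) were gained. Camera then lost the estrogen-repressed list (0.0925), the cell cycle list (0.0985) and the hypoxia list (0.182). Camera also lost the cell cycle list without vehicle replicate 1 (0.0567) and the hypoxia list without vehicle replicate 3 (0.787) or fulvestrant replicate 2 (0.116). With array weights the hypoxia median was -0.0434 (0.497), and TMM scaling (0.067), quantile normalization (0.0654), the GC and length correction (0.0664) and the filter of 100 (0.115) ended that list call too. Quantile normalization also ended that of the cell cycle list (0.0541). A fit of the compared groups alone ended the calls of CELSR2, KRT8, PKM, FBP1, ID1, S1PR3, ELOVL2, EGR1, HES1, GPATCH2, GCC2, AKAP9, NQO1, GOLGA4, NCOA3, KRT18 and FN1 (0.0536 to 0.263). With no filter those of FN1, EGR1, ID1, PKM, ELOVL2, S1PR3, GOLGA4, GPATCH2, GCC2, AKAP9, KRT18 and NQO1 ended (0.0506 to 0.151). Quantile normalization gave FN1 a change of -0.15 (adjusted p = 0.872) and ended AKAP9, GCC2, FBP1, NQO1 and GOLGA4 (0.0693 to 0.143). TMM scaling ended GCC2 and NQO1 (0.0515, 0.0595), and the GC and length correction AKAP9, GCC2, GOLGA4, NQO1 and NCOA3 (0.0742 to 0.191).

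**Figure D1:**
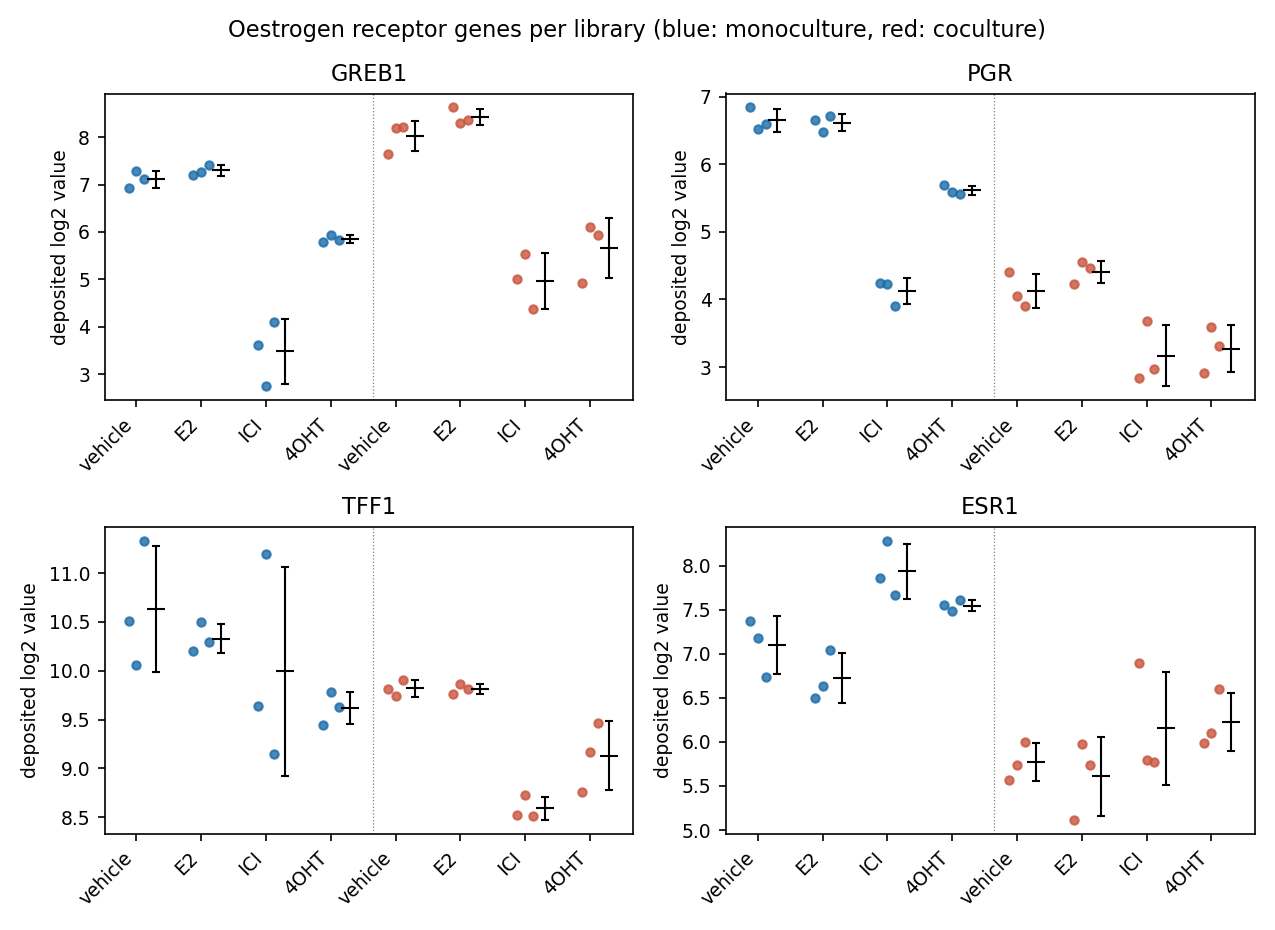
Log2 values of estrogen receptor and target genes in the 8 groups, with 3 libraries per group.

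Fulvestrant also lowered GREB1 in coculture, 8.31-fold from 8.02 ± 0.32 (SD) to 4.97 ± 0.59 (log2 change -3.06 ± 0.32, n = 3 libraries per group, limma with Benjamini-Hochberg adjusted p = 6.83e-07). TFF1, a secreted trefoil peptide induced by estrogen (-1.23 ± 0.34, adjusted p = 0.0244), PGR (-0.96 ± 0.28, adjusted p = 0.0345), the carbonic anhydrase CA12 (-1.11 ± 0.28) and the cyclin CCND1 (-1.05 ± 0.28) fell as well. The other named falling genes code for ribosomal proteins: RPS21 (-2.16 ± 0.43), RPS17 (-1.92 ± 0.34), and RPL32 (-1.89 ± 0.34). Others of this kind were RPL37A (-1.69 ± 0.39), RPL36A (-1.69 ± 0.43), RPS10 (-1.69 ± 0.40) and RPS16 (-1.68 ± 0.35), with adjusted p from 0.0019 to 0.0164. RPL10A, the protein whose tagged form carries the purification, fell by 1.33 ± 0.31 (adjusted p = 0.00973). Over 75 ribosomal protein genes, a set chosen after the values were seen, 44 fell with a median of -1.04 (46 with TMM scaling, 38 with quantile normalization). The camera p with an estimated correlation was 0.0516. Rising genes were the growth factor receptor ERBB2 (1.18 ± 0.34), TBC1D9 (1.00 ± 0.24), SPATA13 (0.93 ± 0.25), ATP9A (0.89 ± 0.23), PDXDC1 (0.79 ± 0.22) and AKAP13 (0.78 ± 0.24), with adjusted p from 0.012 to 0.0451. ESR1 did not pass (0.38 ± 0.29, adjusted p = 0.442).

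Among lists, 6 of 22 estrogen-induced genes fell with fulvestrant in coculture (11 adjusted over the list alone). Their list median was -0.70 (camera adjusted p = 0.000322, and 0.00365 with an estimated correlation). Of 11 cell cycle genes, RRM2, a subunit of ribonucleotide reductase, fell (-1.78 ± 0.45), 4 adjusted over the list alone. The list median was -0.76 (camera adjusted p = 0.0411, adjusted p = 0.258 with an estimated correlation). 0 of 12 hypoxia and glycolysis genes passed, alone or over all genes, with VEGFA at -1.45 ± 0.49 and BNIP3 at -1.55 ± 0.60. This list's median was -0.98 (camera adjusted p = 0.012, adjusted p = 0.507 with an estimated correlation). 0 of 12 mitochondrially encoded genes passed (3 lower adjusted over the list alone), with MT-CYB at -1.08 ± 0.36. Their median was -0.64 (camera adjusted p = 0.00616, adjusted p = 0.507 with an estimated correlation). ERBB2 was the only called member of 6 estrogen-repressed genes (2 adjusted over the list alone, camera adjusted p = 0.179). Of 20 luminal genes, the pioneer factor FOXA1 rose (0.83 ± 0.24) and the keratin KRT19 fell (-1.16 ± 0.32), with 1 higher and 2 lower adjusted over the list alone. JARID2, a PRC2 cofactor, fell (-0.96 ± 0.29), the BMP target ID1 rose (1.26 ± 0.37) and the chaperone HSPH1 fell (-0.89 ± 0.28), with lists that were not called.

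Limma called 61 genes higher and 179 lower with fulvestrant in coculture. The lower share was 74.6%, against 66.7% with TMM scaling, 56.5% with quantile normalization and 58.2% with the GC and length correction. Calls of GREB1, RPS21, RPS17, RPL32, RPS16 and RPL10A held without any 1 of the 6 libraries, and the count was 153 without vehicle replicate 1. That library's removal ended the calls of RPS10, RPL37A, HSPH1, TFF1, TBC1D9, AKAP13, RPL36A, PDXDC1, JARID2, PGR, KRT19, FOXA1 and ID1 (adjusted p 0.0501 to 0.193). Leaving out vehicle replicate 2 ended those of TFF1, KRT19, FOXA1, SPATA13, PGR, ATP9A, CA12, JARID2 and HSPH1 (0.0508 to 0.139). Leaving out vehicle replicate 3 ended those of ID1, CCND1, RRM2, TFF1, SPATA13, HSPH1, AKAP13 and ERBB2 (0.0532 to 0.204). For fulvestrant replicate 1 the lost genes were ERBB2, TFF1, PGR, HSPH1, CCND1, AKAP13 and ID1 (0.0519 to 0.166). They were for replicate 2 SPATA13, RPS10, ERBB2, CA12, KRT19, HSPH1 and FOXA1 (0.0589 to 0.106), and for replicate 3 RPL36A, PDXDC1, TFF1, CCND1, PGR, AKAP13, ERBB2 and JARID2 (0.0516 to 0.18). With quantile normalization TFF1 (-0.56, adjusted p = 0.128), PGR (-0.63, 0.118), CCND1 (0.0823), KRT19 (0.243) and HSPH1 (0.0628) did not pass. With TMM scaling JARID2 (0.0549) and HSPH1 (0.0632) did not, and with array weights 7 genes were left in all, of the named ones GREB1, RPS17 and RPL32. At the filter of 4 PGR, PDXDC1, FOXA1, JARID2, HSPH1 and AKAP13 were lost (0.0561 to 0.0783). In a fit of the compared groups alone ERBB2, ATP9A, CA12, SPATA13, ID1, PDXDC1, AKAP13, FOXA1, JARID2, HSPH1 and PGR were lost (0.0507 to 0.416). With no filter RPS21, CA12, RPS16, AKAP13, RPL10A, FOXA1, RRM2, JARID2, CCND1, HSPH1, RPL37A, RPS10, RPL36A, ERBB2, ID1, TFF1 and KRT19 were lost (0.0506 to 0.181). With the replicate block AKAP13 (adjusted p = 0.0524) and HSPH1 (adjusted p = 0.0559) did not pass. Camera lost the hypoxia list without vehicle replicate 1 (0.202) or fulvestrant replicate 2 (0.0777), with array weights (0.0546) and at the filter of 100 (0.308). It lost the mitochondrial list without the same libraries (0.404 and 0.0966), with quantile normalization (0.694), at the filter of 100 (0.19) and with the GC and length correction, where the median was -0.121 (0.481). The cell cycle list was lost without vehicle replicate 2 or 3 (0.103, 0.132) or fulvestrant replicate 1, 2 or 3 (0.0609, 0.0777, 0.123). It was also lost with quantile normalization (0.0531), array weights (0.0546) and the GC and length correction (0.0914), and the estrogen-induced list at the filter of 100 (0.0987).

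The fulvestrant effect differed between cultures for 113 genes in the interaction test of limma, 40 with a higher and 73 with a lower effect in coculture (n = 3 libraries per group). Effects are signed, so a higher one can stand for a fall in monoculture that was smaller or absent in coculture. KRT8 and ELOVL2 had fallen in monoculture (-2.65 and -1.83 relative to the median gene). Relative to the median difference of -0.28, the cytoskeletal linker PLEC (3.88 ± 0.71), the actin crosslinker FLNA (2.93 ± 0.73) and the elongation factor EEF1A2 (2.89 ± 0.64) had higher effects in coculture. The same held for KRT8 (2.68 ± 0.52), ELOVL2 (2.20 ± 0.55), the secretory pathway protein TMED9 (2.14 ± 0.42), METRN (1.96 ± 0.45) and the guanylate kinase GUK1 (1.88 ± 0.46), with adjusted p from 0.0152 to 0.0471. The named lower ones were ribosomal protein genes: RPS21 (-2.27 ± 0.60), RPS17 (-2.18 ± 0.48), RPS10 (-2.01 ± 0.57), RPS16 (-1.98 ± 0.50) and RPL32 (-1.96 ± 0.47). To these came RPS23 (-1.95 ± 0.55), RPL37 (-1.92 ± 0.56), RPL36A (-1.91 ± 0.60) and RPL10A (-1.33 ± 0.44), with adjusted p from 0.0152 to 0.0416. Of the 73 lower genes 22 were among the 75 ribosomal protein genes (camera p = 0.0881 with an estimated correlation). That p was 0.0436 with TMM scaling, 0.0121 with quantile normalization and 0.0212 with the GC and length correction, with 19, 19 and 11 genes lower. Of 22 estrogen-induced genes, 3 fell less with fulvestrant in coculture (5 adjusted over the list alone): the neuropeptide Y receptor NPY1R (2.72 ± 0.46), IGFBP4 (2.53 ± 0.49) and PGR (1.85 ± 0.39). The list median was 0.89 (camera adjusted p = 1.34e-06, and 0.000327 with an estimated correlation). Relative to the median gene, PGR was already lower in coculture under vehicle (-1.93), and NPY1R over the mean of the treatments (-2.46). Whether a lower starting value limited their fall was not tested. KRT8 and the tight junction protein CLDN3 (2.41 ± 0.58) passed among 20 luminal genes (3 adjusted over the list alone, camera adjusted p = 0.0552). That list was called with TMM scaling (0.0369), quantile normalization (0.000565), array weights (0.0304), the replicate block (0.0471) and the filter of 4 (0.0107), and without monoculture vehicle replicate 1 (0.0161), monoculture fulvestrant replicate 3 (0.0219), coculture vehicle replicate 2 or 3 (0.0489, 0.0484) or coculture fulvestrant replicate 1 (0.0442). IFI6 (2.41 ± 0.60) passed among 4 interferon genes (1 adjusted over the list alone). For GREB1 the unshifted difference was 0.58 (interval -0.34 to 1.5, adjusted p = 0.46), for ESR1 -0.45 ± 0.41 (adjusted p = 0.534) and for TFF1 -0.59 ± 0.48 (adjusted p = 0.48).

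These calls depended on single libraries. Without vehicle replicate 1, 2 and 3 of monoculture the count was 71, 0 and 61. Without monoculture fulvestrant replicate 1, 2 and 3 it was 9, 7 and 524, and without coculture vehicle replicate 1 and 2 it was 32 and 57. Leaving out monoculture vehicle replicate 2 ended the calls of PLEC, KRT8, RPS17, NPY1R, RPL32, IGFBP4, TMED9, RPS16, EEF1A2, PGR, RPS21, RPS10, RPL37, RPS23, GUK1, FLNA, IFI6, CLDN3, METRN, ELOVL2, RPL10A and RPL36A (adjusted p 0.059 to 0.148). Monoculture fulvestrant replicate 2 was next, with 19 of these genes lost (0.063 to 0.194, all but PLEC, RPS17 and NPY1R). Then came monoculture fulvestrant replicate 1 (0.0536 to 0.128, all but PLEC, RPS17, NPY1R, RPL32 and IGFBP4). Coculture vehicle replicate 1 ended RPS16, EEF1A2, RPS23, RPS21, CLDN3, METRN, RPL10A, RPS10, GUK1, RPL37, FLNA, RPL36A and IFI6 (0.0527 to 0.128). The other monoculture vehicle libraries ended RPL37, GUK1, FLNA, PGR, RPL36A, RPL10A and ELOVL2 (replicate 1, 0.0524 to 0.087) and PGR, ELOVL2, EEF1A2, FLNA, METRN, CLDN3, GUK1 and IFI6 (replicate 3, 0.0513 to 0.111). Coculture vehicle replicate 2 ended PGR, FLNA, GUK1, CLDN3, RPL10A, IFI6 and ELOVL2 (0.0505 to 0.0896) and replicate 3 RPL10A, FLNA, CLDN3, ELOVL2, METRN and GUK1 (0.0542 to 0.0849). Among coculture fulvestrant libraries, replicate 1 ended IFI6, METRN and ELOVL2 (0.0648 to 0.0886), and replicate 2 METRN, RPL37, RPS10, CLDN3, IFI6, FLNA, RPL36A, RPL10A and GUK1 (0.0524 to 0.104). There replicate 3 ended RPL10A, CLDN3, FLNA, IFI6 and RPL36A (0.0501 to 0.0722). The share with a lower effect in coculture was 64.6%, against 42.6% with TMM scaling, 42.0% with quantile normalization and 47.3% with the GC and length correction. The GC and length correction took METRN to an unshifted 0.60 (adjusted p = 0.527) and GUK1 to 1.03 (0.161), and ended the calls of FLNA, EEF1A2, RPL37, RPL36A, CLDN3 and IFI6 (0.0606 to 0.141). Array weights ended PGR, ELOVL2 and GUK1 (0.0548, 0.0674, 0.125), and the filter of 4 ended FLNA, PGR, RPL36A, CLDN3, RPL10A, METRN, IFI6, ELOVL2 and GUK1 (0.0527 to 0.0749). With no filter NPY1R alone of the named genes was still called. The replicate block gave 110 genes with GUK1 lost (adjusted p = 0.0551). A fit of the 4 compared groups alone left 0 genes.

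4OHT, a partial antagonist of the same receptor, lowered PRSS23 in monoculture by limma (log2 change -1.77 ± 0.31, adjusted p = 0.0113, n = 3 libraries per group), the 1 gene of 3214 that passed, with 111 at an unadjusted p under 0.05. The estrogen-induced list was nevertheless lower as a group, with 0 of 22 members past the threshold over all genes and 5 adjusted over the list alone. Values were GREB1 at -1.26 ± 0.32, PGR at -1.04 ± 0.28, NPY1R at -1.06 ± 0.32 and CCND1 at -0.95 ± 0.28. The list median was -0.34 (camera adjusted p = 1.03e-07, and 0.000164 with an estimated correlation). TFF1 was at -1.02 ± 0.34, ESR1 at 0.45 ± 0.29 and RPL10A at -0.49 ± 0.31, none past the threshold (adjusted p 0.847 to 0.998). Of 11 cell cycle genes 0 passed, alone or over all genes, with the replication clamp PCNA at -0.98 ± 0.37 and UBE2C at -1.02 ± 0.43. Here the median was -0.69 (camera adjusted p = 3.42e-06, and 0.00263 with an estimated correlation). The 6 estrogen-repressed genes (list median 0.42, camera adjusted p = 0.0012, and 0.0274 with an estimated correlation) and 4 FGF and PDGF signalling genes (0.66, 0.000597, and 0.00704 with an estimated correlation) were higher as lists. Their members passing were 0 over all genes and 0 and 1 adjusted over the list alone. The 12 mitochondrially encoded genes were lower (list median -0.56, camera adjusted p = 3.46e-08, adjusted p = 0.165 with an estimated correlation). The 5 TGF-beta and YAP responsive genes were higher (0.50, 0.0409, adjusted p = 0.108 with an estimated correlation), again with 0 members past the threshold over all genes or adjusted over the list alone.

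The PRSS23 call with 4OHT in monoculture was lost without vehicle replicate 1, 2 or 3 (adjusted p 0.124, 0.0614, 0.102) and without 4OHT replicate 1, 2 or 3 (0.0715, 0.0978, 0.113), which left 0 genes each time. Array weights gave 81 genes, with GREB1 at an adjusted p of 1.03e-05, and a fit of the compared groups alone 20, with GREB1 at 0.00222. The TGF-beta and YAP list was lost by camera without vehicle replicate 1 or 2 (0.149, 0.173) or 4OHT replicate 2 (0.121), at the filter of 4 (0.0862) and with no filter (0.212). The FGF and PDGF list was not called at the filter of 4 (11 members, 0.175) or with no filter (0.478).

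In coculture 4OHT lowered GREB1, again the only gene past the threshold (limma, -2.37 ± 0.32, 5.16-fold, adjusted p = 0.000127, n = 3 libraries per group), with 234 genes at an unadjusted p under 0.05. PGR was at -0.85 ± 0.28 (adjusted p = 0.496), TFF1 at -0.69 ± 0.34 (0.672), the coregulator NRIP1 at -0.68 ± 0.27, CCND1 at -0.70 ± 0.28, ESR1 at 0.46 ± 0.29 and RPL10A at -0.35 ± 0.31. Of 22 estrogen-induced genes 1 passed (1 adjusted over the list alone, list median -0.09, camera adjusted p = 0.018, and 0.0379 with an estimated correlation). That list call was lost without vehicle replicate 3 (0.122) or 4OHT replicate 1 (0.0782) and with quantile normalization (0.0824), and 9 genes passed without vehicle replicate 1. The difference of the 4OHT effect between cultures was called for 0 genes by limma (81 at an unadjusted p under 0.05). For GREB1 it was -1.10 (interval -2.02 to -0.18, adjusted p = 0.998). The mitochondrially encoded list had a median difference of 0.38 (camera adjusted p = 0.00599, adjusted p = 0.573 with an estimated correlation). Camera lost it without monoculture 4OHT replicate 2 (0.126), coculture vehicle replicate 3 (0.425) or coculture 4OHT replicate 2 (0.151) and with the GC and length correction (0.0752). The hypoxia and glycolysis list (median -0.60, camera adjusted p = 0.0838) was called with quantile normalization (0.0298) and array weights (0.0384). It was also called without monoculture vehicle replicate 3 (-1.11, 3.82e-07), monoculture 4OHT replicate 1 or 3 (0.00533, 0.000296), coculture vehicle replicate 2 or 3 (0.0458, 0.0387) or coculture 4OHT replicate 1 (-1.25, 5.64e-05). The cell cycle list (median 0.30, camera adjusted p = 0.493) was called with quantile normalization (0.0298), at the filter of 4 (0.0365) and with no filter (0.0293).

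E2 after hormone-depleted medium gave 0 genes by limma in either culture, with 109 genes in monoculture and 215 in coculture at an unadjusted p under 0.05 (n = 3 libraries per group). GREB1 differed from vehicle by 0.18 ± 0.32 in monoculture and 0.41 ± 0.32 in coculture, PGR by -0.04 ± 0.28 and 0.29 ± 0.28, TFF1 by -0.30 ± 0.34 and -0.00 ± 0.34. ESR1 differed by -0.38 ± 0.29 and -0.16 ± 0.29, and RPL10A by -0.27 ± 0.31 in both. Genes of hypoxia and glycolysis were higher with E2 in monoculture as a list, with 0 of 12 past the threshold over all genes and 12 adjusted over the list alone. Among them were hexokinase HK2 at 1.64 ± 0.41, lactate dehydrogenase LDHA at 1.59 ± 0.47, the angiogenic factor VEGFA at 1.52 ± 0.49 and the glucose transporter SLC2A1 at 1.45 ± 0.45. The list median was 1.5 (camera adjusted p = 6.48e-23, and 0.0337 with an estimated correlation). Vehicle replicate 3 had a list mean of 7.25, apart from replicates 1 and 2 (5.47 and 5.65) and inside the range of the E2 libraries (7.09 to 7.97). The mitochondrially encoded list was lower in monoculture (median -0.38, camera adjusted p = 4.29e-05, adjusted p = 0.766 with an estimated correlation). MT-CYB was at -0.54 ± 0.36 and 0 of 12 members passed alone or over all genes, and that call was lost without E2 replicate 1 (0.172). The interaction of E2 with culture gave 0 genes by limma (194 at an unadjusted p under 0.05). The hypoxia and glycolysis list differed by a median of -1.70 (6 of 12 lower adjusted over the list alone, 0 over all genes, camera adjusted p = 3.28e-11, adjusted p = 0.343 with an estimated correlation). HK2 was at -2.22 ± 0.58 (adjusted p = 0.478). Array weights gave 104 genes for E2 in monoculture, a fit of the compared groups alone 15. Leaving out coculture vehicle replicate 1 gave 3 for E2 in coculture, while the interaction gave 1 without monoculture vehicle replicate 3.

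Most of the tested genes differed between cultures: over the mean of the 4 treatments 649 were higher and 1953 lower in coculture by limma (n = 12 libraries per culture). The labels give no batch, so this difference cannot be credited to the stromal partner alone. Relative to the median gene, which moved by -0.69, the higher genes were the fatty acid synthase FASN (4.01 ± 0.22), FLNA (3.97 ± 0.26), PRRC2B (3.53 ± 0.20) and the calcium-binding protein S100A9 (3.24 ± 0.12). Also higher were the translation factors EIF5A (3.23 ± 0.14) and EIF4G1 (3.02 ± 0.15), CELSR2 (3.18 ± 0.19) and the amino acid transporter SLC7A5 (3.11 ± 0.16). The lower ones were SPTSSB, a subunit of serine palmitoyltransferase (-3.85 ± 0.15), C3orf14 (-3.27 ± 0.20) and the ribosomal protein genes RPL41 (-3.01 ± 0.18) and RPL7 (-2.99 ± 0.20). Lower too were the GTPase RAB1A (-2.93 ± 0.19), the actin regulators BRK1 (-2.90 ± 0.15) and DSTN (-2.85 ± 0.17), and TMEM64 (-2.88 ± 0.14), with Benjamini-Hochberg adjusted p from 1.68e-19 to 2.67e-12 for these 16 genes. Among receptor genes, ESR1 (-0.70 ± 0.14, adjusted p = 9e-10) and PGR (-1.32 ± 0.14, adjusted p = 2.16e-13) were lower and GREB1 higher (1.52 ± 0.16, adjusted p = 2.59e-05). TFF1 lay near the median gene (-0.12 ± 0.17) and RPL10A at -0.27 ± 0.15. EZH2, the PRC2 methyltransferase, was under the filter and at the filter of 4 had an unshifted change of -0.05 ± 0.21 (adjusted p = 0.823). It was at -0.43 ± 0.43 for fulvestrant in monoculture and -0.44 ± 0.43 in coculture (adjusted p = 0.622 and 0.626). Changes followed GC content: across genes, which are not independent replicates, the Spearman correlation with GC was 0.512, and the median change ran from -1.56 in the decile of lowest GC (36.8%) to 0.304 in the highest (61.6%).

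The share of lower genes depended on the scaling: 75.1% of called genes were lower, against 51.9% with TMM scaling and 52.5% with quantile normalization. The GC and length correction kept 1659 of the calls (63.8%) and ended those of GREB1 (0.21, adjusted p = 0.177), PCNA (-0.18, adjusted p = 0.316), IDI1 (-0.39, adjusted p = 0.107) and INSIG1 (-0.41, adjusted p = 0.0605). TMM scaling ended those of TFF1 (-0.16, adjusted p = 0.324) and RBBP4 (-0.32, adjusted p = 0.122).

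**Figure D2:**
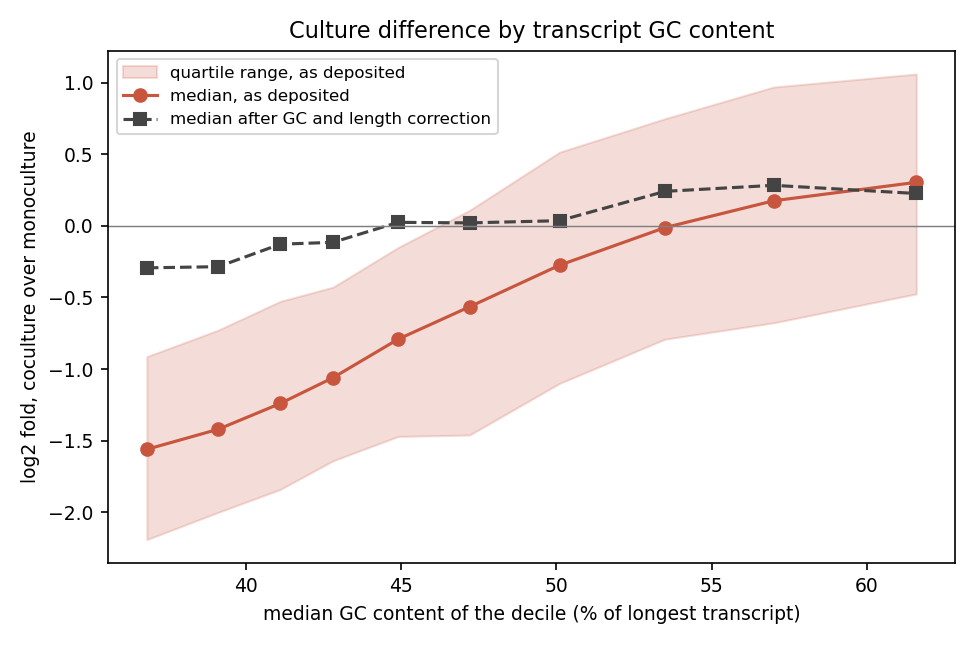
Log2 change between coculture and monoculture by GC content of the gene, with n = 12 libraries per culture.

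By list, changes between cultures were mixed, and the counts here are the same adjusted over the list alone unless both are given. They count unshifted changes, of which 649 were higher and 1953 lower over all 3214 genes tested. Thus more lower members are no result alone. Of 22 estrogen-induced genes 10 were higher and 11 lower (list median 0.27, camera adjusted p = 0.453), with NPY1R at -2.46 ± 0.16 and TPD52L1 at -1.70 ± 0.16. Of 6 estrogen-repressed genes 2 were higher and 4 lower, including ERBB2 (1.98 ± 0.17) and the cyclin CCNG2 (-1.94 ± 0.19). Luminal genes split 5 higher to 10 lower of 20, which shows no loss as a list. PRLR (-1.61 ± 0.14), EPCAM (-1.19 ± 0.17) and GATA3 (-0.97 ± 0.12) were lower, and of 2 basal and stem genes CD44 was at -0.76 ± 0.18. Cell cycle genes split 4 to 4 of 11, with the proliferation marker MKI67 (3.07 ± 0.13), MCM7 (2.41 ± 0.16) and CENPF (2.38 ± 0.16) higher and PCNA (-1.02 ± 0.19) lower (camera adjusted p = 0.0668). At the filter of 4 there were 12 higher and 7 lower of 29, 12 and 6 adjusted over the list alone (camera adjusted p = 0.00251, and 0.0329 with an estimated correlation). Interferon genes split 2 to 1 of 4, with ISG15 (2.78 ± 0.12) and IRF9 (1.82 ± 0.17) higher (camera adjusted p = 0.0668), and of 2 NF-kB genes SOD2 was higher (1.48 ± 0.17). Of 8 handling stress genes 4 were higher and 1 lower, with JUN at 3.21 ± 0.13 and HSPA1A at 1.60 ± 0.17 (camera adjusted p = 0.0517). That list was called with the replicate block (0.0496), array weights (0.044), the GC and length correction (0.0379) and the filter of 4 (0.0173), and without 1 of 10 libraries (0.036 to 0.0499). EGR1 (1.46 ± 0.15) was among 2 higher and 1 lower of 4 FGF and PDGF genes (camera adjusted p = 0.183).

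Mitochondrially encoded genes were higher in coculture as a list, 9 higher and 2 lower of 12, with MT-ND5 at 2.53 ± 0.15 and MT-ND1 at 2.49 ± 0.19. Their list median was 1.5 (camera adjusted p = 0.000238, adjusted p = 0.369 with an estimated correlation, and 0.0659 with no filter). Hypoxia and glycolysis genes were lower in 8 of 12 (7 adjusted over the list alone) and higher in 0, with BNIP3 at -1.91 ± 0.30 and SLC2A1 at -0.84 ± 0.23 (list median 0.05 but mean -0.19, camera down, adjusted p = 0.985). Cholesterol synthesis split 3 higher to 5 lower of 9, with the reductase DHCR24 (1.91 ± 0.14) and the receptor LDLR (1.78 ± 0.15) higher and IDI1 (-1.06 ± 0.23) and INSIG1 (-0.72 ± 0.20) lower (camera adjusted p = 0.425). The chaperone HYOU1 (2.92 ± 0.17) was the 1 higher of 5 stress genes with 1 lower, and ID2 (-1.77 ± 0.20) was among 3 lower of 5 TGF-beta and YAP genes (list median 0.14, mean -0.03, camera up, adjusted p = 0.985). Of 3 PRC2 genes RBBP7 (-0.42 ± 0.19) and RBBP4 (-0.28 ± 0.19) were lower (list median -0.28 but mean 0.05, camera down, adjusted p = 0.985), but RBBP7 reversed with the GC and length correction (0.06, adjusted p = 0.801). 1 of 15 osteoblast markers was tested, the growth factor BMP4 (-1.38 ± 0.16), while 0 of 8 adipocyte and 0 of 12 blood and endothelial markers reached the filter.

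Matrix genes of stromal cells were among the changes of largest size in coculture. COL1A2, a chain of type I collagen, rose by 6.74 ± 0.26 relative to the median gene (adjusted p = 1.62e-17, limma with Benjamini-Hochberg) and fibronectin, FN1, by 4.38 ± 0.17 (adjusted p = 6.33e-17). TIMP3 fell by 0.65 ± 0.18. LGALS1 lay at 0.11 ± 0.24, its unshifted change of -0.57 (adjusted p = 0.0288) turning to 0.07 with TMM scaling (0.783) and 0.22 with quantile normalization (0.381). Its call was lost without monoculture vehicle replicate 3 (0.0692) or fulvestrant replicate 2 (0.0587), or coculture vehicle replicate 3 (0.0674), E2 replicate 1 (0.0544), fulvestrant replicate 2 (0.0587) or 4OHT replicate 3 (0.073). At the filter of 4, 9 of 12 tested stromal markers were higher and 2 lower (9 and 2 adjusted over the list alone). Their median was 3.45 (camera adjusted p = 2.96e-08, and 0.00449 with an estimated correlation). Some of them, such as COL1A2 and SPARC, reached this filter only through their coculture values, so it favours members that rose. With no filter the list median was 1.12 (camera adjusted p = 1.94e-05). Unshifted changes were 4.78 ± 0.26 for COL1A1, 4.74 ± 0.22 for COL3A1, 4.36 ± 0.22 for COL6A3 and 4.27 ± 0.22 for SPARC. VIM, an abundant stromal filament protein, was at -0.22 ± 0.23 (adjusted p = 0.39). Of 5 epithelial-mesenchymal transition genes at this filter 4 were higher (4 adjusted over the list alone), FN1 and SPARC, the protease MMP2 (4.08 ± 0.26) and the integrin ITGA5 (0.95 ± 0.21). FN1 and SPARC are also on the stromal list (camera adjusted p = 8.33e-05, and 0.00917 with an estimated correlation). At the filter of 20 the stromal list had 4 members, 2 higher and 2 lower (camera adjusted p = 0.0755).

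**Figure D3:**
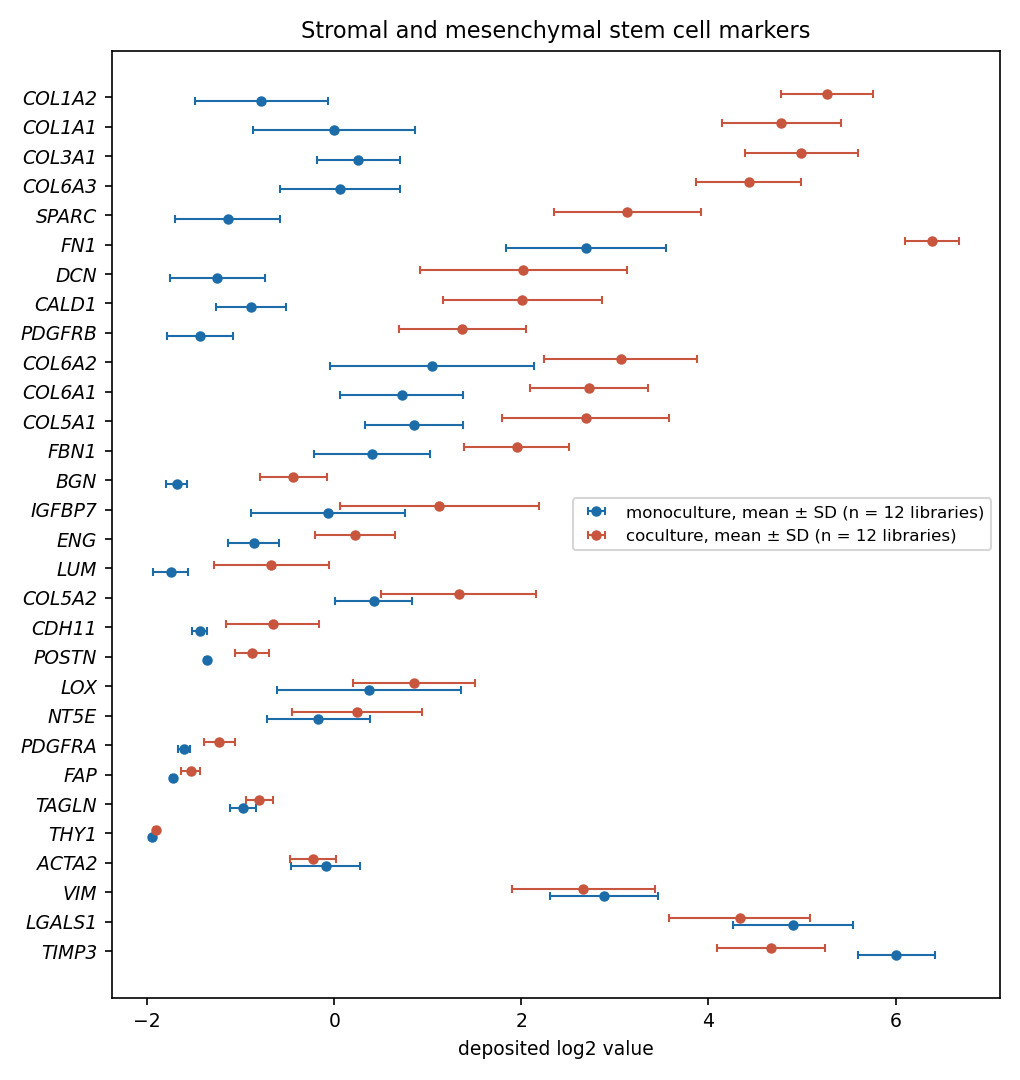
Mean log2 value of stromal markers in monoculture and coculture with SD over n = 12 libraries each, where the changes of LGALS1 and VIM lie near that of the median gene and LGALS1 turns direction with TMM scaling and quantile normalization.

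Within single treatments limma called 1818 genes between cultures under vehicle (414 higher, 1404 lower) and 1944 under E2 (453, 1491). There were 2283 under fulvestrant (525, 1758) and 1817 under 4OHT (427, 1390), with n = 3 libraries per group. Relative to median changes of -0.60, -0.67, -0.94 and -0.60, the first named genes were PRRC2B (3.54 ± 0.41) and SPTSSB (-4.18 ± 0.30) under vehicle and EIF5A (3.56 ± 0.29) and the mitophagy receptor BNIP3L (-3.88 ± 0.65) under E2. They were FASN (5.78 ± 0.43) and SPTSSB (-4.04 ± 0.30) under fulvestrant, and FLNA (3.66 ± 0.51) and SPTSSB (-3.49 ± 0.30) under 4OHT. GREB1 was higher in coculture under vehicle (1.51 ± 0.32), E2 (1.80 ± 0.32) and fulvestrant (2.43 ± 0.32), and under 4OHT at 0.41 ± 0.32 (adjusted p = 0.621). PGR was at -1.93, -1.53, -0.02 and -1.74 and ESR1 at -0.73, -0.44, -0.84 and -0.71 in the same order, all past the threshold before the shift. RPL10A was lower under fulvestrant (-1.26 ± 0.31), with 0.01, 0.09 and 0.16 under vehicle, E2 and 4OHT, and TFF1 lay between -0.47 and 0.15. The lower shares of 77.2%, 76.7%, 77.0% and 76.5% became 50.9%, 50.7%, 52.2% and 50.9% with TMM scaling. They became 51.6%, 51.6%, 53.0% and 52.0% with quantile normalization. Under vehicle the GREB1 call was lost without monoculture vehicle replicate 1 (0.0628), coculture vehicle replicate 2 (0.061) or 3 (0.0613). The TFF1 call (adjusted p = 0.04) was lost without monoculture vehicle replicate 1 or 3 (0.0606, 0.273) or coculture vehicle replicate 1, 2 or 3 (0.0708, 0.0956, 0.0626). It was also lost with TMM scaling (0.484), quantile normalization (0.12), the GC and length correction (0.0684), array weights (0.0752), no filter (0.135) and a fit of the compared groups alone (0.0535). Under fulvestrant the TFF1 call ended with TMM scaling (0.0867), quantile normalization (0.325) and the GC and length correction (0.066). RPL10A under vehicle, not called in the main fit, was gained without monoculture vehicle replicate 2 (0.0337). The GC and length correction ended GREB1 under vehicle and E2 (0.381, 0.131), and scaling by TMM or quantiles ended ESR1 under E2 (0.149, 0.0935). PGR under fulvestrant turned from an unshifted -0.96 to -0.14 with TMM scaling (adjusted p = 0.677) and 0.08 with quantile normalization (adjusted p = 0.805).

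4OHT is a non-steroidal triphenylethylene, given at 100 nM. Fulvestrant is an estradiol analogue with a long side chain at the 7-alpha position and a dose the labels leave unclear. They differed in monoculture for 51 genes, 51 higher and 0 lower with 4OHT (limma, n = 3 libraries per group). That direction turned with array weights (296 higher, 447 lower, 60.2% lower) and without fulvestrant replicate 3 (260 and 319, 55.1% lower). Relative to a median of -0.23, IGFBP4 (2.95 ± 0.34), CELSR2 (2.73 ± 0.37), GREB1 (2.60 ± 0.32, adjusted p = 3.25e-05), the protease CTSD (2.28 ± 0.41) and SLC7A5 (2.26 ± 0.33) were higher. So were RAB31 (2.05 ± 0.36), SLC9A3R1 (2.03 ± 0.30), KRT8 (1.95 ± 0.36), the receptor chaperone FKBP4 (1.90 ± 0.27), PKM (1.81 ± 0.33), TPD52L1 (1.80 ± 0.31), the GDNF receptor GFRA1 (1.73 ± 0.20) and PGR (1.72 ± 0.28). Of 22 estrogen-induced genes 10 were higher with 4OHT (12 adjusted over the list alone, camera adjusted p = 1.85e-16, and 8.46e-07 with an estimated correlation). No difference was called for ESR1 (unshifted interval -0.98 to 0.20), TFF1 (-1.06 to 0.31) or RPL10A (-1.41 to -0.14, adjusted p = 0.201, and 0.00275 without fulvestrant replicate 3). The count was 31, 25 and 579 without fulvestrant replicate 1, 2 and 3 and 32, 30 and 29 without 4OHT replicate 1, 2 and 3. KRT8 was lost without fulvestrant replicate 1 or 2 or 4OHT replicate 2 (0.053, 0.102, 0.0535), and PKM without fulvestrant replicate 2 or 4OHT replicate 2 (0.0899, 0.0956). A fit of the compared groups alone ended FKBP4, TPD52L1, CELSR2, SLC7A5, CTSD, KRT8 and PKM (0.0812 to 0.308), and no filter RAB31, CTSD, PKM and KRT8 (0.0688 to 0.207). The hypoxia list was higher (0.90, camera adjusted p = 0.00288, adjusted p = 0.537 with an estimated correlation), lost without fulvestrant replicate 3 or 4OHT replicate 2 (0.0646, 0.366) and with array weights (0.333). The mitochondrial list was lower (-0.44, 0.00907, adjusted p = 0.666 with an estimated correlation), lost without fulvestrant replicate 2 or 4OHT replicate 2 (0.204, 0.162). It turned to 0.202 with the GC and length correction (0.068), and quantile normalization (0.0822), array weights (0.183), the filter of 100 (0.123) and a fit of the compared groups alone (0.0911) ended the call. Of either list 0 members passed alone or over all genes.

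In coculture the same pair differed for 97 genes by limma, 77 higher and 20 lower with 4OHT. The lower share was 20.6%, against 30.4% with TMM scaling, 35.7% with quantile normalization and 40.7% with the GC and length correction. RPS21 was higher (1.79 ± 0.43, adjusted p = 0.0206), as was CA12 (1.16 ± 0.28, adjusted p = 0.0202), the 1 estrogen-induced gene of 22 that passed (2 adjusted over the list alone, camera adjusted p = 0.0834). The helicase CHD6 was lower (-0.87 ± 0.24, adjusted p = 0.0404). No difference was called for GREB1 (0.69, interval 0.03 to 1.34, adjusted p = 0.248), PGR (0.11, interval -0.46 to 0.68), ESR1 (0.07, interval -0.52 to 0.66), TFF1 (0.54, interval -0.15 to 1.23) or RPL10A (0.98, interval 0.35 to 1.61, adjusted p = 0.0738). The count was 45, 46 and 46 without 4OHT replicate 1, 2 and 3. Calls were lost without fulvestrant replicate 2 (RPS21 0.0518, CA12 0.0877, CHD6 0.152), 4OHT replicate 1 (RPS21 0.0567, CHD6 0.0544), replicate 2 (RPS21 0.0896, CA12 0.113, CHD6 0.113) and replicate 3 (CA12 0.0724, CHD6 0.135). Array weights ended RPS21 (0.0532), CHD6 (0.169) and, barely, CA12 (0.05), the filter of 4 ended CHD6 (0.0679), and a fit of the compared groups alone CHD6 and CA12 (0.0663 each). With no filter RPS21 (0.131), CHD6 (0.0685) and CA12 (0.0591) were lost. The mitochondrial list was higher (0.50, camera adjusted p = 0.0252, adjusted p = 0.461 with an estimated correlation, 0 of 12 members passing alone or over all genes), lost without fulvestrant replicate 1 or 2 or 4OHT replicate 2 (0.0652, 0.339, 0.0966). Its call also ended with quantile normalization and the GC and length correction (0.319 each) and at the filter of 100 (0.519).

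Fulvestrant and E2, which share the steroid core and differ by that side chain, are set side by side although doses may differ. In monoculture limma called 64 genes higher and 135 lower with fulvestrant (67.8% lower, n = 3 libraries per group). The lower share was 81.8% with TMM scaling and 70.4% with quantile normalization, but 43.1% with array weights (479 higher, 363 lower) and 47.1% without fulvestrant replicate 3 (340 and 303). Relative to a median of 0.20, GREB1 was at -4.02 ± 0.32 (adjusted p = 4.14e-09), PGR at -2.7 ± 0.28, IGFBP4 at -2.66 ± 0.34, FKBP4 at -2.20 ± 0.27 and ID1 at 2.10 ± 0.37. Of 22 estrogen-induced genes 15 were lower (16 adjusted over the list alone, camera adjusted p = 1.95e-22, and 8.94e-08 with an estimated correlation). Of 12 hypoxia and glycolysis genes 7 were lower (12 adjusted over the list alone), with SLC2A1 at -2.74 ± 0.45, VEGFA at -2.66 ± 0.49, LDHA at -2.62 ± 0.47 and PGK1 at -2.36 ± 0.48. The list was called (camera adjusted p = 7.06e-13, adjusted p = 0.0825 with an estimated correlation). Of 11 cell cycle genes RRM2 (-2.02 ± 0.45), TOP2A (-1.40 ± 0.33) and MKI67 (-1.24 ± 0.27) were lower (4 adjusted over the list alone, camera adjusted p = 0.000364, and 0.0178 with an estimated correlation). Of 6 estrogen-repressed genes 3 were higher (3 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.0825 with an estimated correlation, and 0.0819 without fulvestrant replicate 3). ESR1 was higher (1.01 ± 0.29, adjusted p = 0.00996), and TFF1 (-0.55 ± 0.34) and RPL10A (0.35 ± 0.31) were not called. Without E2 replicate 1 and 2 the count was 72 and 94, and without fulvestrant replicate 1, 2 and 3 115, 83 and 643. Calls of ESR1, RRM2, MKI67 and TOP2A were lost without E2 replicate 1 (0.076, 0.0552, 0.102, 0.123) or 2 (0.0503, 0.0562, 0.0718, 0.14). Also lost were those of ESR1, MKI67 and TOP2A without fulvestrant replicate 2 (0.0712, 0.0763, 0.0639), and TOP2A without replicate 1 (0.0777), while RPL10A was gained without replicate 3 (0.0118). Quantile normalization ended ESR1 and MKI67 (0.0693, 0.0768), and no filter RRM2 and PGK1 (0.0682, 0.0795).

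In coculture fulvestrant and E2 differed for 243 genes, 85 higher and 158 lower by limma (n = 3 libraries per group). GREB1 was at -3.46 ± 0.32 (adjusted p = 4.16e-08), RPS17 at -1.84 ± 0.34, CELSR2 at -1.60 ± 0.37 and PGR at -1.25 ± 0.28, all lower with fulvestrant. Further values were TFF1 at -1.22 ± 0.34, FKBP4 at -1.22 ± 0.27, TOP2A at -1.12 ± 0.33, RPL10A at -1.06 ± 0.31 and ERBB2 at 1.36 ± 0.34, with adjusted p up to 0.0328, and ESR1 at 0.54 ± 0.29 (adjusted p = 0.256). Of 22 estrogen-induced genes 7 were lower (12 adjusted over the list alone, camera adjusted p = 2.35e-06, 0.000406 with an estimated correlation, and 0.0768 at the filter of 100). The count was 131 and 112 without E2 replicate 2 and 3. Without E2 replicate 1 ERBB2, TFF1 and TOP2A were lost (0.0706, 0.0509, 0.0844), without replicate 2 TFF1 and RPL10A (0.0758, 0.0811), and without replicate 3 ERBB2, TFF1, TOP2A and RPL10A (0.0559, 0.0694, 0.115, 0.116). Fulvestrant replicate 1 decided TFF1 and TOP2A (0.0603, 0.0829), replicate 2 TOP2A and RPL10A (0.0777, 0.11) and replicate 3 TFF1 and RPL10A (0.0609, 0.0638). Array weights ended ERBB2, TFF1, RPL10A and TOP2A (0.0671 to 0.173), no filter these and CELSR2 (0.0664 to 0.112), quantile normalization TFF1 and TOP2A (0.112, 0.0659), and a fit of the compared groups alone PGR and TOP2A (0.192, 0.232).

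Mitochondrial ribosomal RNA took a larger share of the summed values in coculture. It was 4.42% ± 0.697 (SD) under vehicle, 3.61% ± 0.301 under E2, 3.03% ± 0.793 under fulvestrant and 3.81% ± 0.295 under 4OHT in monoculture. In coculture it was 24.4% ± 3.34, 24.2% ± 4.97, 29.1% ± 2.02 and 20% ± 4.53 (n = 3 libraries each). The mean log2 value of ribosomal protein genes was 7.36 under vehicle and 6.28 ± 0.075 under fulvestrant in coculture, against 8.12 and 8.38 ± 0.833 in monoculture.

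**Figure D4:**
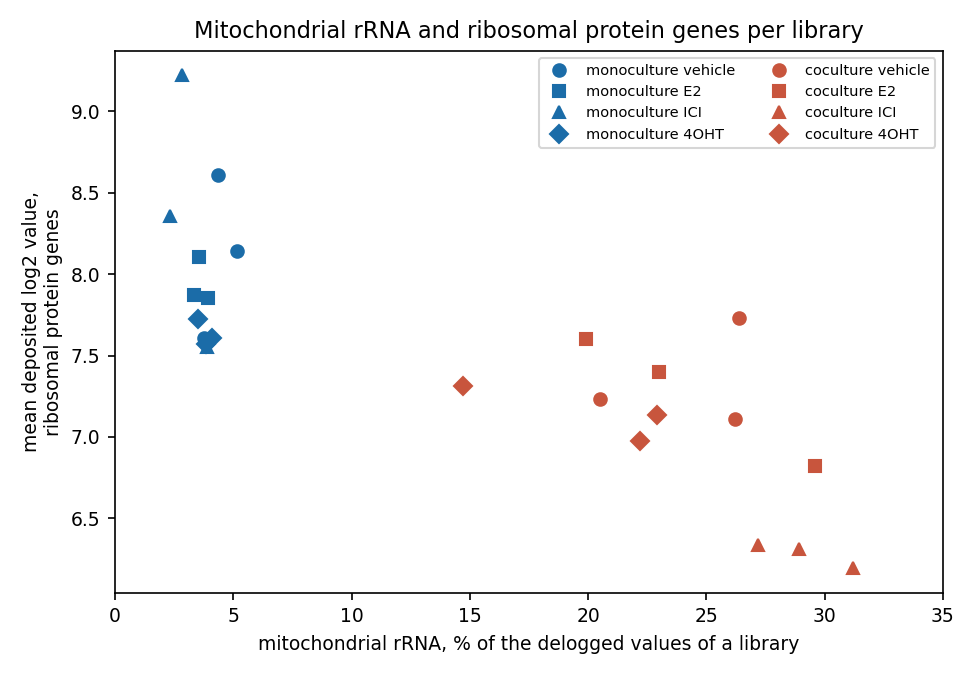
Share of mitochondrial ribosomal RNA in each library and mean log2 value of ribosomal protein genes, by group.

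Positions on GRCh38 of genes named throughout are chromosome 2 from 11482341 to 11642788 for GREB1, chromosome 6 from 151656691 to 152129619 for ESR1, and chromosome 21 from 42362282 to 42366594 for TFF1. They are chromosome 11 from 101029624 to 101130524 for PGR and chromosome 7 from 94394561 to 94431232 for COL1A2.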

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

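The test with mitochondrial ribosomal RNA, the GC and length correction and the comparison of sizes with and without monoculture fulvestrant replicate 2 were chosen only after the result was seen. The interaction test of limma gave a difference between cultures in the fulvestrant effect for 113 genes (n = 3 libraries per group). The unshifted differences of the named genes were 3.605 for PLEC, 2.654 for FLNA, 2.611 for EEF1A2, 2.405 for KRT8, 1.918 for ELOVL2, 1.863 for TMED9, 1.679 for METRN and 1.603 for GUK1. They were -2.552 for RPS21, -2.458 for RPS17, -2.287 for RPS10, -2.256 for RPS16, -2.238 for RPL32, -2.235 for RPS23, -2.199 for RPL37 and -2.186 for RPL36A.

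GC content or length bias was not excluded as a source. After correction all 113 genes kept their sign, and their median size went from 1.89 (median SE 0.473) to 1.42 (0.413). These genes were chosen before the correction, so their kept sign and size cannot argue against this cause. Over all genes tested 55 were called after it, so the trends it removed did not account for every call. Part of the differences may still follow GC, since they did so across genes (Spearman 0.422, and 0.0699 after correction) and 34.5% of the 113 calls were kept, with the median effect smaller by about 1 SE. Monoculture fulvestrant replicate 2 stays open as a source. Without it 7 genes were called and only 6.19% of the calls were kept, which met the share set beforehand for this cause. All 113 genes kept their sign, with a median size of 1.53 (0.45). These genes were chosen with that library included, so their kept sign and size cannot argue against it. Why calls were lost was not tested: most named genes shrank, but ELOVL2 went from 1.918 to 2.096 and lost its call as well. Leaving out monoculture vehicle replicate 2 left 0 genes, so calls rest on several libraries. A larger share of mitochondrial ribosomal RNA could also contribute: within coculture groups it went with lower ribosomal protein genes with r = -0.556 and rho = -0.566 (12 libraries, 2 relations, exact two-sided permutation p = 0.16 and 0.111, both 0.16 after Benjamini-Hochberg), and r was -0.367 without the 2 libraries farthest from the median share, so no relation was shown or excluded. A different response of the cells to fulvestrant beside a stromal partner is the biological explanation the design names and stays among the open ones, untested beyond the interaction itself.

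Of 100 regroupings of the libraries, 4 gave as many genes for the fulvestrant interaction as the real one, the real one included, and the highest other gave 373. Regrouping within each culture also breaks up the fulvestrant effects called there (135 and 240 genes), which the interaction does not ask about. The share therefore cannot exclude chance, and the source of the regrouping with 373 genes was not tested.

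The hypoxia and glycolysis list differed between cultures in its E2 effect by a median of -1.7, called by camera with the preset correlation only. The estrogen-induced list differed in its fulvestrant effect by a median of 0.893, with both correlations. The mitochondrially encoded list differed in its 4OHT effect by a median of 0.383, called with the preset correlation only.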

How the results depend on the processing

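The filter of 4 and the GC and length correction were chosen only after the result was seen. Of 260 named gene results, 257 kept their direction and side of the threshold with the replicate block, 247 with TMM scaling, 244 at the filter of 4, 238 with quantile normalization, 232 with the GC and length correction, 210 with array weights, 192 with no filter and 183 in a fit of the compared groups alone. With the replicate block the counts were 134, 238, 110 and 2591 for fulvestrant in monoculture, in coculture, its interaction and the mean culture difference. Counts of genes that moved by more than 1.5 times follow, as totals. Array weights gave, for E2 in monoculture 104, fulvestrant 503, 4OHT 81, 4OHT against fulvestrant 743 and fulvestrant against E2 842, and in coculture fulvestrant 7, 4OHT against fulvestrant 15 and fulvestrant against E2 105. The GC and length correction gave 3 for 4OHT in monoculture, 2 in coculture, 55 for the fulvestrant interaction, 1400 for culture under fulvestrant and 162 for 4OHT against fulvestrant in coculture. TMM scaling gave 93 for 4OHT against fulvestrant in monoculture. Quantile normalization gave 2 for 4OHT in monoculture and 154 for 4OHT against fulvestrant in coculture. The cause was not tested for these. Fewer genes tested (filter of 100, 377 genes) gave in monoculture 1 for E2, 44 for fulvestrant, 0 for 4OHT, 17 for 4OHT against fulvestrant and 59 for fulvestrant against E2, in coculture 100 for fulvestrant, 61 and 92 for the same pairs, 58 for the fulvestrant interaction, and 317, 237, 244, 294 and 238 for culture (mean, vehicle, E2, fulvestrant, 4OHT). The filter of 4, with 8843 genes, gave 2 for 4OHT in monoculture, 6630, 3916, 4248, 5205 and 4002 for culture, 326 for fulvestrant against E2 in monoculture and 149 for 4OHT against fulvestrant in coculture. With no filter the counts were 82 for fulvestrant and 0 for 4OHT in monoculture, 2 for 4OHT in coculture, 11 for the fulvestrant interaction, 14922, 4930, 5412, 12638 and 5430 for culture and 132 for fulvestrant against E2 in coculture. A fit of the compared groups alone, with fewer libraries, gave 15 for E2, 12 for fulvestrant, 20 for 4OHT and 11 for 4OHT against fulvestrant in monoculture, 91 for fulvestrant and 121 for fulvestrant against E2 in coculture, and 0 for the fulvestrant interaction.

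Leaving out 1 library gave, in monoculture, 0 to 0 genes for E2, 37 to 559 for fulvestrant, 0 to 0 for 4OHT, 25 to 579 for 4OHT against fulvestrant and 72 to 643 for fulvestrant against E2. In coculture the ranges were 0 to 3, 153 to 246, 1 to 9, 45 to 108 and 112 to 245. The interactions gave 0 to 1 for E2, 0 to 524 for fulvestrant and 0 to 0 for 4OHT. Culture gave 2553 to 2627 for the mean and 1579 to 1767, 1727 to 1812, 2039 to 2353 and 1577 to 1646 under vehicle, E2, fulvestrant and 4OHT.

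Reversed values were, between cultures, 0.0554 for RBBP7 with the GC and length correction, 0.0726 and 0.216 for LGALS1 with TMM scaling and quantile normalization, and 0.0761 for PGR under fulvestrant with quantile normalization. Among lists they were 0.19 for interferon (fulvestrant in monoculture, no filter), -0.364 for hypoxia (4OHT in monoculture without 4OHT replicate 2, with a range of -0.364 to 0.672 over libraries left out), -0.501 for cell cycle (4OHT against fulvestrant in monoculture, quantile normalization), -0.271 for interferon (the same pair, no filter) and 0.202 for mitochondrially encoded genes (the same pair, GC and length correction). By camera the hypoxia list for 4OHT in monoculture was called lower without 4OHT replicate 2 (adjusted p = 0.0454). It was called higher without vehicle replicate 3 (1.66e-08) or 4OHT replicate 1 or 3 (0.0147, 0.000496). The cause was not tested. Of 196 list results, 17 lost their call with an estimated correlation. Lists gained a call in 28 results at the filter of 4, 24 with no filter, 8 in a fit of the compared groups, 7 with the GC and length correction, 6 with quantile normalization and 5 with array weights. Other pseudocounts and tests on counts were not run, since the file holds log2 values and no counts, so what depth limits cannot be given. The lowest values were near -2.74, and whether changes near that floor are compressed was not tested.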

Other observations

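The tests of GC and length on many genes, of stromal partner RNA, of the ribosomal protein set and of the hypoxia list within monoculture were chosen only after the result was seen. At the filter of 4, further lists changed between cultures. Of 11 FGF and PDGF genes 4 were higher and 2 lower, 4 and 2 adjusted over the list alone (list median 0.90, camera adjusted p = 0.0317, adjusted p = 0.0705 with an estimated correlation), and of 13 interferon genes 6 and 4, the same adjusted over the list alone (1.01, 0.0173, adjusted p = 0.0705 with an estimated correlation). Of 12 PRC2 genes 1 was higher and 7 lower (camera adjusted p = 0.919), of 7 basal and stem genes 2 and 4 (0.919), and of 7 NF-kB genes 2 and 1 (0.16), with the same counts adjusted over the list alone. The osteoblast markers BMP4 and TNFRSF11B (-1.49) were both lower before any shift, 2 of 2 tested. Below that filter and untested, BMP2 and CDH11 of the same list went the other way, by 2.94 and 0.78. PPARG, a regulator of fat cells and the 1 adipocyte marker tested, was at -0.29 ± 0.22 (adjusted p = 0.221). 0 of 12 blood and endothelial markers reached the filter, and those with values in the file lay below 0 on the log2 scale in both cultures, with differences of 0.04 (CD3E) to 0.35 (PECAM1). With fulvestrant in monoculture 1 of 12 stromal markers was lower (5 adjusted over the list alone, camera adjusted p = 2.31e-05, and 0.00886 with an estimated correlation) and 2 of 5 epithelial-mesenchymal transition genes (4.25e-05, and 0.0052 with an estimated correlation). The stromal list median was -1.04, but -0.246 with no filter (camera adjusted p = 0.0052). Some of these markers, such as COL1A1, COL1A2 and SPARC, reached the filter through coculture and lay below 0 on the log2 scale in monoculture.

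Many genes differed between cultures. GC or length bias is argued against as the whole cause, since 63.8% of the called genes kept call and direction after correction. Part of the differences may follow GC, since the correction left a trend (Spearman 0.192, decile medians from -0.293 to 0.283). The larger number of lower genes could come from scaling: with TMM scaling 51.9% of called genes were lower, but that scaling sets the centre by construction, so the test decides nothing. The labels give no batch, and none was tested. The biological difference the design names, growth beside the stromal partner, stays open and untested.

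The 9 stromal markers called higher in coculture at the filter of 4 had a median log2 change of 4.27. That size holds for these called members: with no filter the list median was 1.12. ACTA2, TAGLN, THY1, NT5E, LOX and FAP differed by -0.13 to 0.48. THY1 and FAP had monoculture means of -1.94 and -1.73 with SDs of 0.0038 and 0.0129. Small differences in genes that low and that even say little. GC or length bias is argued against as the cause: after correction the median was 3.98 and 9 of 9 were still called. RNA of the stromal partner in the purified RNA is a possible explanation. Of 26 markers low in monoculture, 15 (57.7%) rose above the 95th percentile of genes of like level. VIM, TAGLN and THY1 did not. With no library of the partner alone, partner RNA cannot be told apart from expression by the MCF-7 cells. How far purification by the tagged protein removed such RNA was not tested. A share of such RNA that varies between libraries may be present: within coculture groups the 9 genes moved together with a mean correlation of 0.148, against a 95th percentile of 0.118 in 1000 random gene sets, whose highest was 0.365. FN1 and SPARC are on the epithelial-mesenchymal list too, as is VIM, which was not called, so a change of the cancer cells stays open.

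A hypothesis from the coculture fulvestrant values was that ribosomal protein genes move as a group. The camera p with an estimated correlation was 0.0516 over 75 genes, so the group may move together but the test did not pass, and with TMM scaling, quantile normalization and the GC and length correction it was 0.0249, 0.00433 and 0.0181. With 4OHT in monoculture the set was lower too, by a median of -0.463 relative to all genes with 0 members called. Its camera p with an estimated correlation was 0.0661, and 0.0343, 0.0868 and 0.0548 with the same 3 alternatives in order. Purification by tagged RPL10A and shared reads with pseudogenes were not tested as sources.

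A second hypothesis was that hypoxia and glycolysis genes vary together between replicates. Within monoculture groups their mean pairwise correlation was 0.853, against a 95th percentile of 0.512 in random sets (median 0.225, highest 0.74). Between-sphere conditions could therefore differ from library to library in ways the labels do not give, and the list means ranged from 5.47 to 7.25 under vehicle, from 7.09 to 7.97 under E2, from 5.36 to 6.2 under fulvestrant and from 5.59 to 7.39 under 4OHT.

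Regroupings of 3 against 3 libraries number 10, too few for a share under 0.05. Real and highest other counts were 0 and 0 for E2 in monoculture, 135 and 118 for fulvestrant, 1 and 0 for 4OHT, and in coculture 0 and 2, 240 and 19, and 1 and 6. Between cultures they were 1818 and 0 under vehicle, 1944 and 0 under E2, 2283 and 5 under fulvestrant and 1817 and 0 under 4OHT. For 4OHT against fulvestrant they were 51 and 0 in monoculture and 97 and 3 in coculture, and for fulvestrant against E2 199 and 0, and 243 and 16. For the mean culture difference 1 of 100 regroupings, the real one, gave as many as 2602 (highest other 1646), so chance is excluded. For the E2 and 4OHT interactions the real count was 0, which 100 of 100 regroupings reach by necessity (highest other 1 and 4), so these regroupings decide nothing.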
